A study of Mus musculus with 144 samples.

How the data were processed

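RNA of mouse cells that express the orphan nuclear receptor Tlx (gene Nr2e1), sorted by flow cytometry from the subventricular zone, was sequenced from 131 single cells and from 13 bulk pools of 500 cells. The cDNA was made with a SMARTer Ultra Low Input kit, sheared, and turned into libraries with NEBNext Ultra reagents, per the labels' protocols. The authors deposited a single table of TPM values (transcript abundances scaled to a fixed sum), with 37621 rows and 144 columns. The values were made with RSEM 1.2.15 against the mouse build mm9, per the submitters' processing notes. Annotation, aligner, filters and read depth were not stated. TPM keeps no read counts, so the depth per library is unknown, and the number of genes at 1 TPM or more was used to describe each library. The columns summed to between 710525 and 1000000, so part of the total of some libraries lay outside the table, and values were used as deposited.

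Ensembl gene IDs were matched to symbols for 32897 rows. The 4723 unmatched rows held a median of 1.77% of a library's TPM. A further row carried the name gfp. No annotation of mm9 was used, so no coordinates are given. All 26 gene lists and the named-gene rule were written before the data were examined, as were the comparisons, tests, thresholds and a first set of alternatives. Of the list members, 6 matched no row.

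Groups came from the labels, which give a stage (aNSC, qNSC or filtered out) and an age (5-week, 7-week or 7-month) for each single cell and an age for each bulk pool. The title of each library starts with a set name, and the sets titled A1, A2 and A3 held labelled cells of 7 months, 7 weeks and 5 weeks, in 9 sets in all. The labels name no animal, sex or strain. Cells were therefore not treated as replicates. A pair of 5-week qNSC libraries from set A3_3 had a correlation of log2(TPM + 1) of 0.992, against 0.742 for the next pair of cells, and was averaged and counted as 1 cell. Libraries above 0.95 were treated this way, a rule set after the pair was seen.

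Stages were compared with limma 3.58.1 in R 4.3.3 (with data.table, version 1.17.8). The mean of log2(TPM + 1) over the cells of each stage and age gave 6 values, with age as a replicate block and 3 pairs. Bulk ages were compared with limma on title-set means, with 3 sets at 5 weeks, 2 at 7 weeks and 2 at 7 months. Bulk pools were compared with single cells over the 7 title sets that held both, without a block for title set. The cell value was the log2 of the mean TPM over labelled cells, plus 1. Tests were two-sided with Benjamini-Hochberg adjustment and a threshold of 0.05, on genes with a mean log2(TPM + 1) of at least 1. Gene lists with at least 3 tested members were tested with limma's camera, which compares the list with all other tested genes, at a preset inter-gene correlation of 0.01, adjusted over the lists. The lists covered S-phase, G2/M, ribosomal protein, ribosome biogenesis, motile cilia and ependymal, astroglial, activation and progenitor, neuroblast, mature neuron, oligodendrocyte, oligodendrocyte precursor, microglia, endothelial and mural, erythroid, glycolysis, oxidative phosphorylation, fatty acid oxidation, lipid synthesis, Notch, growth factor, BMP, interferon response, immediate early, proteasome, splicing factor and lysosome genes.

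Shares of cells used 1 TPM as the detection level, with exact binomial (Clopper-Pearson) 95% intervals that cover counting error only. Where a share was 0, the limit was set by 3 cells of the total. Single-cell ages, the aNSC share and the filtered-out libraries were described without a test. The labels do not say whether title sets are separate mice, and the tests of bulk took them as independent. Every bulk pool of 5 weeks and 7 weeks held the female-expressed Xist and Y-linked transcripts together, at 1 TPM or more. These pools therefore mixed mice of both sexes, and a title set of these ages need not be a single mouse. For single-cell ages, a gene was called separated where the means of the 3 title sets of one age all lay above or all below the 3 of the other. Chance gives this for 10% of genes.

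Named stage genes were drawn from the 10 largest changes per direction among genes past the threshold with the same sign in all 3 ages and in at least 8 of 9 title sets. To these were added a fixed panel and up to 4 members of each list. Bulk ages gave up to 6 genes per direction and contrast, bulk against cells 8 per direction, and single-cell ages 3 per direction. Predicted gene models were left out of these lists.

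The alternatives of that first set were a pseudocount of 0.1, no filter, a filter at a mean of 3, the log2 of the mean TPM in place of the mean of logs (or the reverse), quantile normalization, other units and blocks, a covariate for genes detected, leaving out the 10% of cells with the fewest genes, rescaling without mitochondrial and ribosomal RNA rows, leaving out each age or title set, an estimated inter-gene correlation, and a detection level of 10 TPM. Alternatives added after seeing the data were keeping the near-identical libraries apart, leaving out 2 aNSC cells high in oligodendrocyte genes, and rescaling the TPM of each library to a sum of 1000000, with and without Malat1.

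Each fit was tested on data with known shifts added. The stage fit used the real cells with stage labels shuffled within age, and the other fits used simulated normal values. In the stage comparison, 1.49% of genes shifted by 1 on the log2 scale were recovered, 16.4% of those shifted by 2 and 75.8% of those shifted by 3, with 1 false call among 4147 genes. In the bulk ages, 1.49%, 22.4% and 59.1% were recovered, with 6 false calls among 13801 genes. In bulk against cells, 1.49%, 31.3% and 48.5% were recovered, with 4 false calls among 12610 genes. There, simulated bulk and cells shared a mean for each unshifted gene. These false calls therefore do not bear on a difference that all genes share in the real data. Figures were drawn with matplotlib 3.10.9 in python 3.11.15.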

Results

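The labelled single cells comprised 58 aNSC and 59 qNSC libraries, the usual short names for active and quiescent neural stem cells. At 5 weeks there were 32 aNSC and 17 qNSC libraries, at 7 weeks 16 and 23, and at 7 months 10 and 19. A pair of near-identical 5-week qNSC libraries was counted as 1 cell, which left 116 cells, 58 of each stage. A further 14 single-cell libraries were labelled as filtered out, and 13 bulk libraries came from 5-week (9), 7-week (2) and 7-month (2) mice. The values were TPM without read counts, so the depth was unknown. The median number of genes at 1 TPM or more was 2752 in aNSC (range 1621 to 3842), 2195 in qNSC (1016 to 4161), 5305 in filtered-out libraries (4720 to 12188) and 13873 in bulk (13497 to 14221). The nuclear long non-coding RNA Malat1 took a median of 9.51% of the TPM in qNSC and 1.62% in aNSC.

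The cells were sorted for expression of Tlx, encoded by Nr2e1 (ENSMUSG00000019803), a nuclear receptor that keeps adult neural stem cells self-renewing. Nr2e1 transcripts were seen at 1 TPM or more in 33 of 58 aNSC (56.9%, 95% interval 43.2 to 69.8) and 28 of 58 qNSC (48.3%, 35 to 61.8). A row named gfp, whose source the labels do not describe, was seen in 30 aNSC (51.7%, 38.2 to 65.0) and 20 qNSC (34.5%, 22.5 to 48.1). Mean Nr2e1 was 115 TPM ± 63.0 (SD, n = 3 ages) in aNSC and 123 ± 37.1 in qNSC, a log2 difference of 0.80 (SE 0.53, adjusted p = 0.299) that turned to −0.24 on the log2 of the mean TPM and −0.092 after quantile normalization. The gfp row was at 147 ± 51.8 TPM in aNSC and 57.3 ± 54.9 in qNSC, a difference of 1.32 (SE 0.53, adjusted p = 0.110). Neither Nr2e1 nor gfp separated the stages.

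The series set out to describe how neural stem cells differ from one another in vivo, and the stage comparison asked which transcripts part aNSC from qNSC. Most tested S-phase and ribosomal protein genes were higher in aNSC, and most tested astroglial genes were higher in qNSC. Of 4214 genes tested, 833 were higher and 161 lower in aNSC, with 1620 at an unadjusted p under 0.05. The median difference over all tested genes was 0.71 toward aNSC, so single changes are best read against that shift. No gene passed without the filter or on the log2 of the mean TPM, quantile normalization gave 596 higher and 473 lower genes, and leaving out the 7-week pair left 294 higher. The labels do not say how stages were assigned, and if the same transcriptomes were used, these p-values overstate the evidence.

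The largest falls in aNSC were in genes that define astrocytes and quiescent radial glia-like cells. Aldoc, the brain isoform of aldolase, averaged 161 TPM ± 47.4 (SD, n = 3 ages) in aNSC and 5483 ± 1148 in qNSC, a log2 difference of −7.58 (SE 0.59, adjusted p = 0.00175). Clu, a secreted chaperone, fell by 7.40 (adjusted p = 0.00175) and the gap junction gene Gja1 fell by 7.04 (adjusted p = 0.00175). Differences were −6.48 for Gstm1, −5.75 for the metallothionein Mt3 and −5.74 for the lipid carrier Apoe. They were −5.60 for the sodium pump subunit Atp1b2, −5.56 for the syndecan Sdc4 and −5.40 for the lipid phosphatase Plpp3, with adjusted p between 0.00175 and 0.00384 for these 6 genes. Each gene named so far in this comparison had the same sign in 9 of 9 title sets. From the fixed panel, the glutamate transporter Slc1a3 differed by −5.24 (SE 0.45, adjusted p = 0.00175), the water channel Aqp4 by −2.87 (SE 0.71, adjusted p = 0.0255) and the BMP target Id3 by −2.01 (SE 0.54, adjusted p = 0.0341). The Aqp4 call ended without any 1 of the 3 ages, and the Id3 call without the 7-week pair. Both ended without a replicate block, and Id3 also with title sets as blocks and genes detected as a covariate.

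Stmn1, a microtubule regulator of dividing and migrating cells, averaged 8131 TPM ± 1112 (SD, n = 3 ages) in aNSC and 1753 ± 1178 in qNSC, a log2 difference of 5.94 (SE 0.80, adjusted p = 0.00430). The splicing factor Hnrnpa1 was 5.70 higher, the kinase Cdk4 that drives entry into S phase 5.34 higher and the DNA clamp Pcna 5.28 higher. H2afz and Hmgn2, a histone variant and a nucleosome-binding protein, were 5.28 and 5.06 higher, and the actin-binding peptide Tmsb10 was 5.22 higher. Rps9, Rps6 and Rps3a1 of the small ribosomal subunit were 5.52, 5.38 and 5.17 higher. Adjusted p for these 9 genes lay between 0.00175 and 0.00534, and all had the same sign in 9 of 9 title sets. Reads of ribosomal protein genes, H2afz and Hmgn2 can be shared with near-identical copies, which these data do not resolve. From the panel, Ccnd2 (cyclin D2) was 4.89 higher (SE 0.51, adjusted p = 0.00289), the topoisomerase Top2a 3.14 higher (SE 0.59, adjusted p = 0.0106) and the surface protein Cd24a 2.17 higher (SE 0.47, adjusted p = 0.0161). The calls of Top2a and Cd24a ended without the 5-week or the 7-week pair, and that of Cd24a also with genes detected as a covariate.

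**Figure D1:**
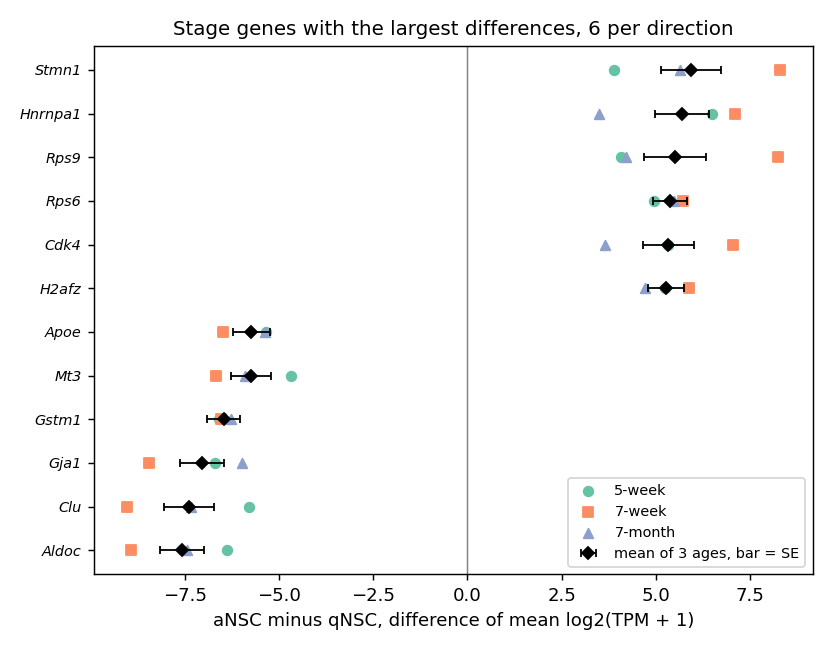
Difference in mean log2(TPM + 1) between aNSC and qNSC for the 6 stage genes per direction with the largest changes under the naming rule, with a point per age and the mean ± SE of 3 ages. Values run from −7.58 for Aldoc to 5.94 for Stmn1.

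Several markers in common use for these cell types did not pass. Egfr, the receptor that marks activated stem cells, differed by 1.08 (SE 0.48, adjusted p = 0.144), the neuroblast gene Dcx by 1.32 (SE 0.51, adjusted p = 0.0999) and the mitotic kinase Cdk1 by 1.57 (SE 0.60, adjusted p = 0.0966). Sox2 differed by −0.20 (SE 0.51, adjusted p = 0.796), Vim by 0.75 (SE 0.53, adjusted p = 0.331) and Fgfr3 by −0.76 (SE 0.50, adjusted p = 0.293). Gfap, Prom1, Nes, Hes1, Hes5, S100b, Foxj1, Dlx2, Olig2, Mki67, Vegfa, Flt1 and Kdr lay below the filter and were compared only as shares of cells. Egfr was seen in 15 of 58 aNSC (25.9%, 15.3 to 39.0) and 4 of 58 qNSC (6.90%, 1.91 to 16.7). The proliferation marker Mki67 was seen in 21 aNSC (36.2%, 24.0 to 49.9) and 4 qNSC (6.90%). Hes1, a Notch effector, was seen in 2 aNSC (3.45%, 0.420 to 11.9) and 15 qNSC (25.9%, 15.3 to 39.0). Calcium-binding S100b was in 0 aNSC, which allows up to 5.17%, and in 10 qNSC (17.2%, 8.59 to 29.4). Gfap, a classical marker of these stem cells, was in 0 aNSC and 3 qNSC (5.17%, 1.08 to 14.4). The VEGF receptors Flt1 and Kdr were in 0 of 58 cells of either stage, which allows up to 5.17%, and their ligand Vegfa was in 2 aNSC (3.45%) and 9 qNSC (15.5%, 7.35 to 27.4).

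Gene lists placed these genes in programmes, by a test with a preset correlation between genes, and the adjusted p with an estimated correlation follows each in brackets. None of the 13 list calls passed with the latter. In the S-phase list, 23 of 27 tested genes were higher in aNSC (25 adjusted over the list alone), with a median difference of 2.63 and a camera adjusted p of 2.46e-08 (0.300). The ribonucleotide reductase subunits Rrm2 and Rrm1 were 4.51 and 3.74 higher and the clamp loader Rfc4 3.72 higher. In the G2/M list, 4 of 22 were higher (4 adjusted over the list alone), Hmgb2, Top2a, Smc2 and Smc4, with a median of 1.43 and an adjusted p of 0.00894 (0.554). All of these but Hmgb2 ended without the 7-week pair. Smc4 also ended with genes detected as a covariate and Smc2 without a replicate block. Of 76 ribosomal protein genes, 69 were higher (74 adjusted over the list alone), with a median of 3.54 and an adjusted p of 6.72e-21 (0.300). Ribosome biogenesis had 10 of 16 higher (11 adjusted over the list alone), among them Nop56 and Npm1, with a median of 1.79 and an adjusted p of 0.000693 (0.300). Splicing factors had 15 of 25 higher (17 adjusted over the list alone), a median of 2.43 and an adjusted p of 4.43e-05 (0.300). The proteasome had 16 of 30 higher (20 adjusted over the list alone), a median of 2.14 and an adjusted p of 0.000135 (0.300). Oxidative phosphorylation had 22 of 64 higher (32 adjusted over the list alone), a median of 1.79 and an adjusted p of 0.000197 (0.436). Activation and progenitor genes had 5 of 7 higher (5 adjusted over the list alone), including Cdk4, Ccnd2, Cdk6 and Dlx1, a median of 3.14 and an adjusted p of 0.0147 (0.300). Neuroblast genes had 5 of 15 higher (5 adjusted over the list alone), including Dpysl3, Tubb3 and Elavl4, a median of 1.41 and an adjusted p of 0.0132 (0.436).

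On the side of qNSC, again with the estimated correlation in brackets, 22 of 27 astroglial genes were lower in aNSC (24 adjusted over the list alone), with a median of −3.57 and an adjusted p of 3.28e-33 (0.300). The lysosome list had 2 of 12 lower, Cd63 and Ctsd (2 adjusted over the list alone), a median of −0.99 and an adjusted p of 5.22e-06 (0.300). The calls of Cd63 and Ctsd ended without the 5-week or the 7-week pair. The Ctsd call also ended without a replicate block, and the Cd63 call with genes detected as a covariate. Fatty acid oxidation had 1 of 13 lower, Acaa2 (0 adjusted over the list alone), a median of −0.49 and an adjusted p of 0.00329 (0.300), and the Acaa2 call ended without any 1 of the 3 ages. Of 4 BMP pathway genes tested, Id2 and Id3 were lower (2 lower and 1 higher adjusted over the list alone), with a median of −1.67 and an adjusted p of 0.00894 (0.300), and both calls ended without the 7-week pair. Glycolysis did not pass as a list (median −0.06, adjusted p = 0.0809) but held opposite changes. Aldoa and Ldhb were lower in aNSC by −3.50 and −2.37 and the pyruvate kinase Pkm was 2.98 higher, and adjusted over the list alone 2 genes were higher and 2 lower. The Ldhb call ended without the 5-week or the 7-month pair and the Pkm call without the 7-week pair. Interferon response genes (3 tested, median −0.55, adjusted p = 0.0591) and lipid synthesis genes (11 tested, adjusted p = 0.316) had 0 genes past the threshold, and 0 adjusted over the list alone. In lipid synthesis the median of 0.78 and the mean of 0.15 were positive while the test, which reads the list against all other genes, pointed down. Of the lists with fewer than 3 tested genes, Notch held Notch2, lower by −3.59 (adjusted p = 0.00438), and immediate early genes held Btg2, 1.62 higher (adjusted p = 0.0396), a call that ended without any 1 of the 3 ages, without a block and after quantile normalization. The 2 tested genes each of the motile cilia, oligodendrocyte and growth factor lists and the 1 tested mature neuron gene did not pass, and 0 oligodendrocyte precursor, microglia, endothelial and erythroid genes were tested.

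**Figure D2:**
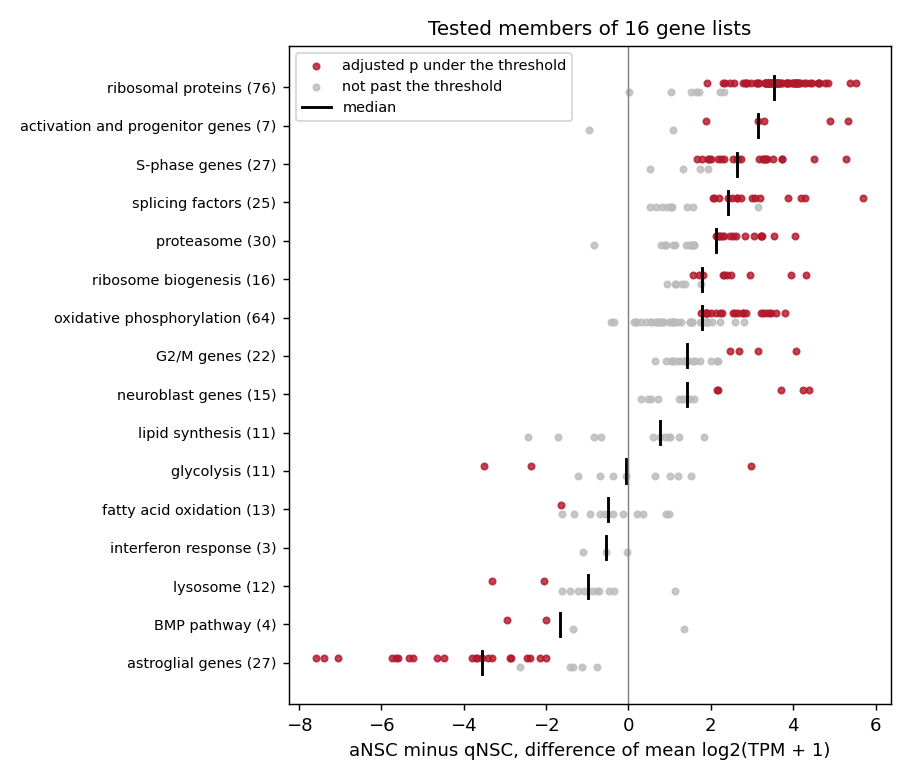
Difference in mean log2(TPM + 1) between aNSC and qNSC for each tested member of 16 gene lists. Astroglial genes have a median of −3.57 and ribosomal protein genes a median of 3.54.

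**Figure D3:**
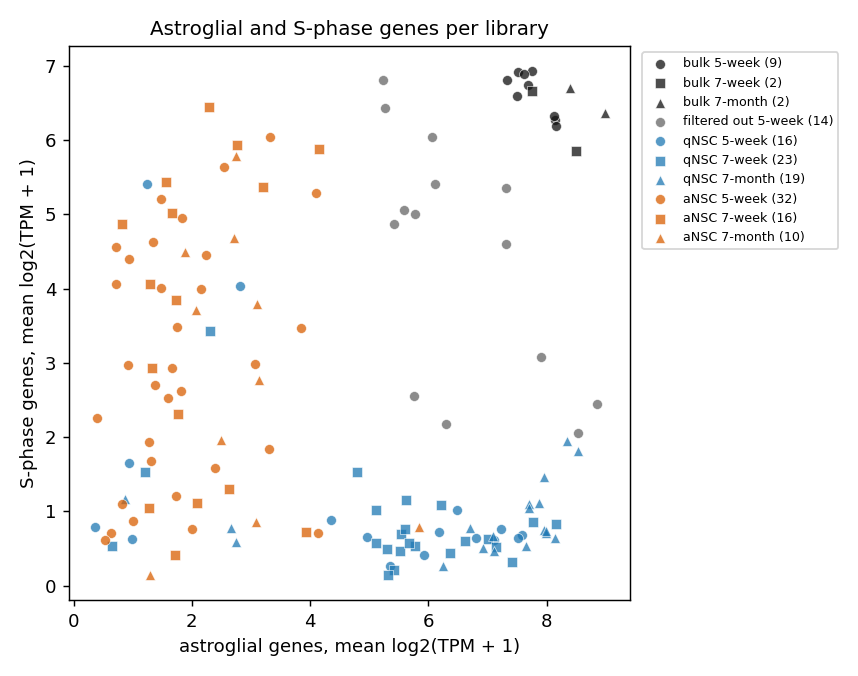
Mean log2(TPM + 1) over the astroglial list against that over the S-phase list, with a point per library. Both means were 3 or more in 6 of 58 aNSC, 0 of 58 qNSC, 10 of 14 filtered-out and 13 of 13 bulk libraries.

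Neurogenesis in the subventricular zone declines with age, and the share of labelled cells called aNSC was compared across ages. The share was 66.7% at 5 weeks (32 of 48 cells, 95% interval 51.6 to 79.6), 41.0% at 7 weeks (16 of 39, 25.6 to 57.9) and 34.5% at 7 months (10 of 29, 17.9 to 54.3). By title set it was 61.1 to 72.2% at 5 weeks, 33.3 to 46.7% at 7 weeks and 25 to 40% at 7 months. Counting the 14 filtered-out libraries among the 5-week cells, by their age label, gave 51.6% at that age, but 7 of the 14 carry titles of the 7-month series, so this share rests on a doubtful label. No test was made, and age cannot be told apart from sort or batch.

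Within each stage, cell age was compared to ask whether aNSC or qNSC change as mice mature, again without a test. Age followed the title series. Y-linked transcripts were at 1 TPM or more in 0 of 29 labelled cells of 7 months. They were in 16 of 48 of 5 weeks and 14 of 39 of 7 weeks. In both stages age could therefore not be told apart from batch, nor at 7 months from the sex of the mice. In 7-month aNSC, the 3 separated genes with the largest decrease from 5 weeks all act in mitosis. The chromosomal passenger genes Cdca8 and Birc5 had mean log2(TPM + 1) of 0.05 and 0.23 at 7 months against 5.36 and 5.29 at 5 weeks, and the kinetochore gene Spc25 0.05 against 5.12. Mki67 was seen in 17 of 32 aNSC at 5 weeks (53.1%, 34.7 to 70.9), 4 of 16 at 7 weeks (25%, 7.27 to 52.4) and 0 of 10 at 7 months, which allows up to 30%. The mean over the G2/M list was 3.13 ± 2.52 (SD over 32 cells), 2.42 ± 2.23 (16 cells) and 0.76 ± 0.58 (10 cells) at the 3 ages, whereas the S-phase list was at 3.00 ± 1.63, 3.54 ± 2.12 and 2.90 ± 1.90. A 7-month cell labelled qNSC, of set A1_1, had a G2/M mean of 7.27. Whether the fall comes from how stages were labelled was not tested. In bulk, Mki67 was at 122 TPM at 5 weeks and 105 at 7 months (limma adjusted p = 0.998), while the G2/M list differed by a median of −0.28. Tmem50a, Spcs2 and the chaperone Calr, of the endoplasmic reticulum, were higher at 7 months by 5.64, 4.29 and 4.0. The 10 cells of 7 months included 2 of set A1_3 dominated by oligodendrocyte genes, with list means of 8.91 and 10.1. The next labelled cell had 2.05. The part of these 2 cells in the changes was not tested. Of 1455 aNSC genes, 70 were separated upward and 100 downward between these ages (11.7%), near the 10% that chance gives.

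In qNSC, the connexin gene Gjb6, Abhd3 and the protease inhibitor Serpine2 were 6.67, 6.27 and 6.25 higher at 7 months than at 5 weeks, and Poldip3 and the long non-coding RNA Tug1 lower by −3.89 and −3.59. Of 1070 qNSC genes, 135 were separated upward and 49 downward (17.2%, chance 10%). Between 7 and 5 weeks, Hmgn3, the receptor Lgr4 and Timp3 were 4.15, 3.71 and 3.62 higher in qNSC, and Rps18, Stmn1 and Prkar1a lower by −4.76, −4.67 and −4.36, with 29 of 792 genes separated upward and 92 downward (15.3%). The qNSC class held a different mix at each age, with an astroglial mean under 3 in 5 of 16 cells at 5 weeks, 3 of 23 at 7 weeks and 3 of 19 at 7 months, and a neuroblast mean of 1.75, 0.76 and 1.96, so these changes need not lie within a cell type. In aNSC between these ages, the translation factors Eif2s1 and Eif3i and the signal peptidase Sec11a were 4.28, 3.65 and 3.35 higher and Fam120a and Rpl35a lower by −4.48 and −3.07, with 68 of 1490 genes separated upward and 64 downward (8.86%). A row without a matched symbol completed the lower genes of the 7-month qNSC and of the 7-week aNSC comparison.

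Bulk pools asked the same question of age on sorted populations, with 3, 2 and 2 title sets at 5 weeks, 7 weeks and 7 months. The test took title sets as independent replicates, and if they share mice its p-values overstate the evidence. Few of 13668 genes passed: 3 higher and 2 lower at 7 weeks than at 5 weeks, 4 and 7 at 7 months than at 5 weeks, and 3 and 7 at 7 months than at 7 weeks. At an unadjusted p under 0.05 there were 1242, 857 and 1616 genes. Ttr (transthyretin, a thyroid hormone carrier abundant in choroid plexus) was 0.518 TPM ± 0.449 (SD, n = 3 sets) at 5 weeks, 91.2 ± 12.5 (n = 2) at 7 weeks and 40.9 ± 15.4 (n = 2) at 7 months. Its differences from 5 weeks were 6.13 (SE 0.37, adjusted p = 0.00486) and 4.95 (SE 0.37, adjusted p = 0.00552). Ifi35, an interferon-induced gene, was higher at 7 months by 2.89 against 5 weeks (adjusted p = 0.0305) and 3.47 against 7 weeks (adjusted p = 0.0323). Eno1b, a copy of the enolase gene Eno1 that can share its reads, was 16.5 TPM ± 5.22 at 5 weeks and listed at 0 at both other ages (adjusted p = 0.0134 and 0.00766). Exoc6 was lower at 7 months than at 5 weeks by −2.54 (adjusted p = 0.0364) and BC002163 lower than at 7 weeks by −6.22 (adjusted p = 0.0391).

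The Y-linked genes Eif2s3y, Ddx3y, Uty and Kdm5d were listed at 0 in both 7-month sets. At 5 weeks they were at 67.2, 35.5, 13.95 and 6.00 TPM, with adjusted p of 0.00552, 0.00552 and 0.00766 for the first 3 against 7 months. Against 7 weeks the adjusted p of all 4 lay between 0.0161 and 0.0391. Predicted gene models made up the remainder, Gm5514, Gm4735, Gm13394, Gm7879, Gm15425 and Gm20463, named after their values were seen. Each of the 15 calls of named genes ended when at least 1 title set was left out (adjusted p 0.0510 to 0.425), and none changed direction.

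**Figure D4:**
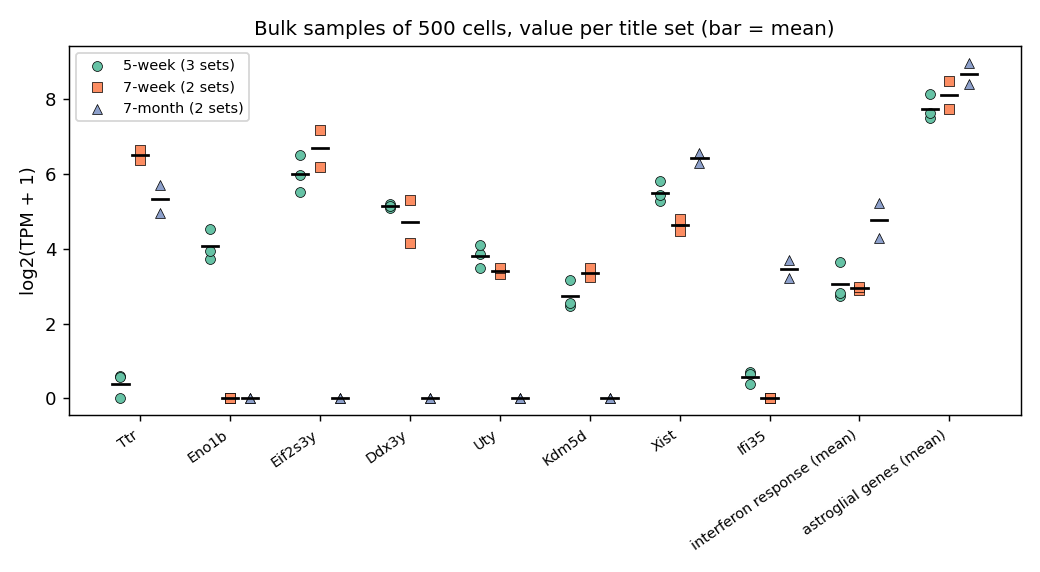
log2(TPM + 1) of each bulk title set by age for selected genes and for the means of the interferon response and astroglial lists. The interferon list averaged 3.07, 2.94 and 4.76 at 5 weeks, 7 weeks and 7 months.

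Interferon response genes were higher as a list at 7 months. Of 21 tested, 0 passed over all genes and 12 were higher adjusted over the list alone, with a median difference of 1.48 from 5 weeks (camera adjusted p = 4.13e-16, and 0.540 with an estimated correlation). The deubiquitinase Usp18 was at 8.56 TPM ± 5.03 at 5 weeks and 109.9 ± 20.1 at 7 months, a difference of 3.83 (SE 0.55, adjusted over the list alone p = 0.00353, over all genes 0.138). The immunoproteasome subunit Psmb8, Ifit1 and Oasl2 were higher by 3.29, 3.29 and 3.17 (adjusted over the list alone p = 0.00425, 0.0255 and 0.0120). Against 7 weeks the interferon median was 1.49 (adjusted p = 6.97e-09, and 0.908 with an estimated correlation), with 10 genes higher adjusted over the list alone. The astroglial list was higher at 7 months by a median of 0.94 from 5 weeks (adjusted p = 5.85e-11, and 0.540 with an estimated correlation), with 0 of 31 genes past the threshold.

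In the other lists past the list threshold, 0 genes passed over all genes. From 5 weeks to 7 months, glycolysis (0.45, adjusted p = 0.00798), the Notch pathway (0.46, 0.0124), the lysosome (0.38, 0.0249) and fatty acid oxidation (0.34, 0.0302) were higher and ribosomal proteins (−0.16, 0.00422) and G2/M genes (−0.28, 0.010) lower. From 5 to 7 weeks, ribosomal proteins (0.30, adjusted p = 3.27e-06), neuroblast genes (0.68, 0.0197), glycolysis (0.29, 0.0219), oxidative phosphorylation (0.13, 0.0219) and astroglial genes (0.38, 0.0219) were higher. G2/M (−0.62, 0.000307), S-phase (−0.35, 0.0219) and oligodendrocyte genes (−1.01, 0.00136) were lower at 7 weeks, the last with 2 genes adjusted over the list alone. Without 1 title set the 7-week medians ranged from −1.17 to 0.0039 for G2/M, −0.69 to 0.039 for S-phase, −0.10 to 1.24 for neuroblast genes and 0.0031 to 0.32 for oxidative phosphorylation. The 7-month medians ranged from −0.63 to 0.056 for G2/M and −0.29 to −0.024 for ribosomal proteins, and each of these 6 reversed the direction of its median or test in at least 1 such fit. From 7 weeks to 7 months, astroglial genes were higher (0.57, 0.0190) and ribosomal proteins (−0.48, 8.22e-11) and neuroblast genes (−0.76, 0.00715) lower. With an estimated correlation, none of the 8, 8 and 4 list calls of the 3 contrasts passed, with adjusted p from 0.540 to 0.952.

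Bulk pools were set against the labelled single cells of the same title sets to ask which transcripts the single-cell libraries miss. Across genes the profiles correlated at 0.867, where genes are not independent replicates. Of 12394 genes, 5886 were higher in bulk and 117 lower, and the median difference was 1.76. Quantile normalization, which removes that shift, gave 1159 higher and 1411 lower. Ifrd1 (153 against 9.98 TPM), the mitochondrial leucyl-tRNA synthetase Lars2 (274 against 5.08) and Tsen34 (145 against 4.79) were higher in bulk by 6.08, 5.89 and 5.78. Prpf19, Mrpl3, Rtca, Ccdc107 and Zfp146 were higher by 5.59, 5.45, 5.44, 5.33 and 5.32, and adjusted p for these 8 genes lay between 1.19e-08 and 3.57e-05. Lower in bulk were Pgk1-rs7 by −3.42, Fyb by −3.09, Adnp by −2.12, the neuroblast factor Sp8 by −2.05 and Malat1 by −2.00 (adjusted p 0.000207 to 0.0354), with 3 rows without a matched symbol. On the mean of logs Adnp and Sp8 turned direction, to 0.74 and 3.01.

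Single genes of neural stem cells are to be read against the same shift. Hes5, a Notch effector, was at 198 TPM ± 161 (SD, n = 7 sets) in bulk and 10.6 ± 16.7 in cells, 5.23 higher (adjusted p = 0.000265). Mki67 was 3.57 higher (adjusted p = 0.00308), Prom1 3.33 (adjusted p = 0.000395) and gfp 3.62 (adjusted p = 0.00809), while Nr2e1 was 1.43 higher and did not pass (adjusted p = 0.117). Slc1a3 differed by −0.28 (adjusted p = 0.581) and Aqp4 by −0.28 (adjusted p = 0.801), and both were higher in bulk on the mean of logs (3.08 and 3.76). The oligodendrocyte lineage genes Olig1 and Olig2 were 3.20 and 2.63 higher in bulk and Pdgfra 2.05 higher (adjusted p 0.0229 for Pdgfra).

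Relative to the median of all genes, 6 lists lay lower in bulk. They were oxidative phosphorylation (median 0.08, adjusted p = 6.51e-13), ribosomal proteins (0.47, 0.000340), the proteasome (0.19, 2.20e-05), astroglial genes (0.57, 4.69e-05), the lysosome (1.10, 0.0293) and motile cilia genes (1.39, 0.0371). Their medians and means were positive while the test pointed down, since all genes together were higher in bulk. With an estimated correlation none passed (adjusted p 0.0861 to 0.690), and quantile normalization reversed the first 5 in median or test, as the mean of logs did the lysosome. Adjusted over the list alone, 0, 2, 0, 6, 6 and 4 of their genes were higher, in that order, against 6, 9, 3, 7, 6 and 4 over all genes. Lower in bulk were 0, 0, 0, 2, 1 and 1 adjusted over the list alone and 3, 0, 1, 2, 1 and 1 over all genes. Of the lists of other cell types, few members passed the filter, which bulk values help to decide. Higher in bulk were 2 of 2 tested oligodendrocyte precursor genes (7 in the list), 1 of 1 microglia genes (15), 3 of 3 endothelial and mural genes (20), 3 of 5 mature neuron genes (12), 2 of 5 oligodendrocyte genes (12) and 1 of 3 erythroid genes (7). The counts were the same adjusted over the list alone, and 5886 of all 12394 genes were higher in bulk as well.

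The 14 filtered-out libraries were described beside the labelled cells to ask what set them apart. Each detected more genes than any labelled cell, and the mean over the astroglial list was high in all, with a median of 6.08 (range 5.24 to 8.85) against 6.23 in qNSC and 1.78 in aNSC. The S-phase mean had a median of 4.94 (2.06 to 6.81), against 0.70 in qNSC and 2.97 in aNSC. Both list means were 3 or more in 10 of 14 filtered-out libraries, in 6 of 58 aNSC and in 0 of 58 qNSC, as in all 13 bulk pools. In these libraries Nr2e1 ranged from 1.56 to 778 TPM and gfp from 4.69 to 1309 TPM.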

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

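The tests weighed here on sex, genetic background, age labels and mixed cells were chosen after the results were seen, while the counts of other splits were planned. The 20 checks for a single library far from its group covered only the 7-month aNSC (10 cells) and the 5-week bulk (9 libraries). Other groups were not checked, by a rule on group size. The measures were genes detected, total TPM, gfp, Nr2e1 and the means of some lists. The checks found 2, where chance gives about 1 in 20. The comparison of stage differences between ages covered 85 named genes.

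The 7-month aNSC libraries held 1 cell far above the others in astroglial genes, with a mean log2(TPM + 1) of 5.84 against 1.29 to 3.14 in the other 9. Among the 9 bulk libraries of 5-week mice, 1 of set A3_3 had an oligodendrocyte mean of 3.81 against 1.88 to 2.48 in the others. The Notch effector Hes5 was higher in aNSC in every title set at 5 weeks (0.76) and lower in every set at 7 weeks (−0.82), with 0.51 at 7 months. The homeobox gene Dlx2 was higher in aNSC in every set at 5 weeks (1.4) and lower in every set at 7 months (−0.59), with 1.00 at 7 weeks. Neither difference between ages was tested, and Hes5 and Dlx2 lay below the filter.

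A pattern appeared in the filtered-out libraries of set A3_1. Xist, expressed from the inactive X chromosome of females, and Y-linked genes were both at 1 TPM or more in 6 of 7 of these libraries and in 0 of 116 labelled cells, of which 27 held Xist alone and 30 Y-linked transcripts alone. RNA of more than one cell in a library stays open, since the 6 of 7 are the pattern itself. The 7 libraries held 5216 to 12188 genes at 1 TPM or more, against at most 4161 in a labelled cell. That goes with more than one cell but does not decide it, since the depth per library was unknown. Filtered-out libraries titled A1 also exceeded every labelled cell. No A1 library held Y-linked transcripts at 1 TPM or more, so mixed cells could not show this pattern there. More genes detected in a single cell of either sex would leave the lower of Xist and the Y-linked sum at 0. It was 2.64 to 18.5 TPM in the 6 libraries, with a median of 6.34 over all 7. These values define the pattern, and they argue against that explanation. A trace of RNA from other cells would leave the lower near 0, but its median was 34% of the higher, which argues against it too. If cells were mixed, a female and a male cell come from different mice, so joining in the tissue would not give this pattern. Whether cells came together in the sort or at another step was not tested.

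A further pattern was in the 7 filtered-out libraries titled A1, which carry a 5-week age label. Gm5514, a predicted gene chosen after its values were seen, was at 27.7 to 142 TPM in 7 of 7 of them, as it was in 26 of 29 cells labelled 7-month but in 2 of 48 cells labelled 5-week. It was also in 12 of 39 cells labelled 7-week, so it does not mark 7 months alone. Whether the age label differs from the age of the mice stays open, since the 7 of 7 were seen before. The Y-linked sum was 0 to 0.36 TPM in these 7, and under 1 in all libraries labelled 7-month, but 1.85 to 143 in the 7 filtered-out libraries of set A3_1. Female mice of 5 weeks would give the same, so this does not decide it. Higher gene detection in filtered-out libraries is argued against, since 0 of the 7 filtered-out libraries of set A3_1 held Gm5514. The age label of the A1 libraries entered only the alternative share of aNSC at 5 weeks, which is doubtful for that reason.

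The third pattern is the set of bulk genes that differ between ages. Sex of the mice may explain the 4 Y-linked genes among the 15 genes past the threshold, since 0 of 31 libraries of 7 months, bulk and labelled cells, held Y-linked transcripts at 1 TPM or more while 16 of 48 cells of 5 weeks held these alone. Of the other 11 genes, 7 were all or nothing between ages in bulk, among them Eno1b and Gm5514. In labelled cells Eno1b was at 1 TPM or more in 1 of 48 of 5 weeks, 8 of 39 of 7 weeks and 7 of 29 of 7 months, against its order in bulk. Genetic background of the mice and age cannot be told apart for these 7, since no label gives a strain and each title series holds bulk pools of 1 age. Cells and bulk disagreed for Eno1b, which can share reads with Eno1. Whether its reads were assigned differently in cells and in bulk was not tested. Age itself stays open and untested for all 11 genes and for the interferon response list. At 7 months neither sex nor batch can be told apart from age for them.

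For the stage comparison, 10 splits of the 6 profiles were possible, too few for a share under 0.05, and 1 of 10, the real one, gave 994 genes, with 0 in the highest other. Of the 10, 4 parted every pair of ages, and the other 3 of these gave 0. With title sets as replicate blocks, the paired fit called 1163 genes, and 1 of 100 flips drawn from 256 reached that number, the real one, with 590 in the highest other. For bulk against cells, 1 of 100 splits drawn from 1716 reached 6003 genes, the real one, with 2165 in the highest other. Chance is thereby argued against for the stage comparison by title set, but if stages were assigned from the same transcriptomes, the count of flips is circular. For bulk against cells the splits decide nothing. Bulk detected a median of 13873 genes, against 2752 in aNSC and 2195 in qNSC, so the real split would give the most calls anyway. These splits also ignored that bulk and cells shared title sets.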

How the results depend on the processing

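The alternatives with near-identical libraries kept apart, without 2 oligodendrocyte-high cells and with TPM rescaled to a fixed sum, with or without Malat1, were chosen after seeing the data. The cause of each change below was not tested unless stated.

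Stage genes numbered 833 higher and 161 lower. Without a filter 0 and 0 passed, and on the log2 of the mean TPM 0 and 0. A filter at a mean of 3 left 93 lower genes and 5 lists, with fewer genes tested. Quantile normalization gave 473 lower, and title sets in a replicate block with genes detected as a covariate gave 419 higher. Without 1 age, 294 to 896 genes were higher, 86 to 120 lower, and 12 to 14 lists passed. An estimated correlation left 0 lists. Nr2e1 reversed to −0.24 on the log2 of the mean TPM and −0.092 after quantile normalization, and Sox2 ranged from −0.16 to 0.19 without 1 age. Of 1189 values of named stage genes under the alternatives, 1011 kept direction and side of the threshold, 174 lost the call, 1 gained it and 3 reversed. Title sets as the unit in a replicate block gave 938 higher and 225 lower, and no block 659 and 112.

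For bulk ages, a pseudocount of 0.1 gave 6 lower genes at 7 weeks against 5 weeks, 13 lower at 7 months against 5 weeks, and 15 higher and 18 lower at 7 months against 7 weeks. No filter gave 7 higher at 7 months against 5 weeks, and 0 higher, 0 lower and 7 lists against 7 weeks. A filter at 3 gave 0 lower at 7 weeks, and 2 higher and 3 lower at 7 months against 5 weeks, from fewer genes tested. All 13 libraries as samples gave 7 higher at 7 months against 7 weeks, and quantile normalization 4 lists at 7 weeks. An estimated correlation left 0 lists in each contrast. Without 1 title set, which can leave an age with a lone set assumed to vary like the others, the ranges were 0 to 3 higher, 0 to 0 lower and 5 to 8 lists at 7 weeks against 5 weeks, 1 to 2, 0 to 7 and 2 to 8 at 7 months against 5 weeks, and 0 to 0, 0 to 3 and 4 to 7 at 7 months against 7 weeks. List medians at 7 months against 5 weeks ranged from −0.63 to 0.056 for G2/M and −0.29 to −0.024 for ribosomal proteins. At 7 weeks they ranged from −0.69 to 0.039 for S-phase, −1.17 to 0.0039 for G2/M, −0.10 to 1.24 for neuroblast genes and 0.0031 to 0.32 for oxidative phosphorylation, and each of these lists reversed the direction of its median or test in at least 1 such fit.

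For bulk against cells, title set as a replicate block gave 5965 calls, of which 5709 were among the 6003 of the unblocked fit. No filter gave 177 lower genes. A filter at 3 gave 1834 higher, 49 lower and 3 lists. Quantile normalization gave 1159 higher and 1411 lower, since it removes the shift of all genes, and reversed Hes1 to −0.93, Vegfa to −0.67, and the lists of ribosomal proteins (median 0.46), astroglial genes (0.26), oxidative phosphorylation (−0.056), proteasome (0.20) and lysosome (0.39) in median or test. The mean of logs gave 11688 higher and 13 lower, and reversed Adnp to 0.74, Sp8 to 3.01, Slc1a3 to 3.08, Aqp4 to 3.76 and the lysosome list (median 4.09). An estimated correlation left 0 lists. At 10 TPM, 13 of 54 shares moved beyond their interval. Depth was unknown, so its effect on genes seen in few cells, such as Gfap and Prom1, was not measured.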

Other observations

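These observations were made after the values were seen, and none was tested. Within qNSC, the astroglial list split the cells with a gap. In 11 of 58 qNSC cells, from 8 title sets, the mean log2(TPM + 1) of astroglial genes was 2.82 or less, and in the other 47 it was 4.35 or more. In 9 of the 11 the mean over the neuroblast list was 3 or more, with 6.79 the highest, and in 0 of the other qNSC cells. In 3 of the 11 the G2/M mean was above 4, with 7.27 in a 7-month cell of set A1_1. The qNSC label thus covered cells with an astroglial profile and some with a neuroblast profile.

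In set A1_3, 2 aNSC cells of 7 months were dominated by oligodendrocyte genes, with list means of 8.91 and 10.1 against 2.05 in the next cell. The myelin gene Mbp was at 3973 and 6813 TPM in these cells. Transthyretin (Ttr) was at 1 TPM or more in 0 of 48 cells of 5 weeks, in 6 of 39 of 7 weeks and in 10 of 29 of 7 months, which follows the order of the bulk pools at 5 weeks against the older ages.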
